A study of Mus musculus with 4 samples.

How the data were processed

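The series holds 4 CLIP-seq libraries from mouse embryonic stem cells. CLIP-seq sequences the RNA that ultraviolet light has joined to a protein. Per the labels' protocols, cells made the bacterial biotin ligase BirA together with a tagged YY1 or OCT4 that BirA biotinylates, and control cells made BirA only. The cells grew on irradiated mouse embryonic fibroblasts, were irradiated at 254 nm, and their nuclei were isolated and lysed before the tagged protein was captured on streptavidin beads. The RNA was then copied into cDNA. Each group had 1 library. Processed files of 1 library, YY1, were used. The other 3 libraries, the BirA control for YY1, OCT4 and the BirA control for OCT4, were not analysed here.

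The YY1 library came as 2 peak lists made by the authors, 1 for each genome strand. The deposited lists have 3 columns, chromosome, start and end, and no height, fold enrichment, p-value or read count for a peak. Cutadapt, Bowtie, Bowtie2 and SAMtools are named in the submitters' processing notes, with no version or role, and the genome build named there is mm9. The peak caller, its threshold, the handling of reads that map to several places and any use of the control library are not given in the sources used here. The strand of a peak was taken from the name of its list, which the labels do not explain. In the mitochondrial genome the ribosomal RNA genes lie at the start of the reference and are read from its plus strand, and positions 1 to 2047 had a plus-strand peak and no minus-strand peak. Read depth is unknown. A peak's width was the only measure of its extent, and width depends on the caller's threshold, on read depth and on the length of the bound RNA. The lists cannot show how much of a peak would be present in the control.

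Starts were converted from the 0-based BED form, so all positions are 1-based mm9 coordinates. No mm9 gene annotation or sequence was used here. The gene table at hand belongs to GRCm38, and coordinates were not carried between builds, so peaks are named by position and not by gene. For the same reason 3 planned results were not computed: the share of peaks in genes, the share on the gene's own strand, and counts for fixed gene lists, among them pluripotency genes and fibroblast markers of the feeder cells.

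The following were computed from the lists. The share of plus-strand peaks and the share on each chromosome were given with exact Clopper-Pearson 95% intervals, and medians with 95% intervals from binomial ranks. Density was the number of peaks per Mb between the first and last peak of a chromosome. Peaks on opposite strands overlapped if they had at least 1 base in common. Among the peaks that overlapped nothing on the other strand, a pair was 2 peaks that were each other's nearest neighbour on the opposite strand, with a gap of at most 2000 bases. A pair was divergent if the minus-strand peak had the lower coordinate and convergent otherwise. Clusters were same-strand peaks joined across gaps of at most 10000 bases. Observed values were set beside 1000 random placements of peaks within the span of their own chromosome. For overlaps and pairs, the minus-strand peaks were placed. For clusters, the peaks of both strands were. All intervals cover counting error over the peaks of 1 library and treat peaks as independent, although neighbouring peaks can come from 1 RNA. With 1 library there is no estimate of the error between replicates, so no p-value is given.

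Peaks named in the text followed a rule. Since the lists hold no score, the 25 widest peaks over both strands and the 5 clusters with the most peaks were named. A tie extended the clusters to 7. Named pairs and overlaps, the clusters joined across gaps of 50 kb, and single chromosomes were chosen after their values were seen. The main settings and most alternatives were fixed before the data were examined. The alternatives were a stricter list holding the wider 50% of peaks of each strand, the list without the mitochondrial chromosome, joining of peaks within 100 bases, and other limits for overlaps, gaps, clusters and placements. The counting of overlaps, pairs and clusters was tested on simulated data. All 200 divergent pairs, 100 convergent pairs, 60 overlaps and 40 clusters planted among 3880 simulated peaks were found. Planted items lay apart from each other, so pairing in crowded regions was not tested. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.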

Results

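RNA crosslinked to YY1, a zinc finger transcription factor, was mapped in nuclei of mouse embryonic stem cells that carried a biotin-tagged form of the protein. The study asked where in the genome the RNA bound by the factor is transcribed, with attention to regulatory elements. The peak lists of the 1 YY1 library held 12053 peaks covering 5594 kb of the mm9 genome. The plus strand had 6148 peaks and the minus strand 5905. The plus-strand share was 51.0% (95% interval 50.1 to 51.9). It was 51.1% when same-strand peaks within 50 kb were counted once (49.8 to 52.3). With only the wider 50% of peaks kept it was 51.0% (49.8 to 52.3). The share hardly changed, and with fewer peaks both of these wider intervals held 50%. A comparison with the cells that made only the biotin ligase, and one between YY1 and OCT4, need values of those libraries, which were not analysed here.

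Peaks were short, and their widths were alike on both strands. The median width was 335 bases on the plus strand (95% interval 328 to 346) and 336 bases on the minus strand (327 to 346). The middle range, from the lower to the upper quartile, ran from 204 to 570 bases on the plus strand and from 202 to 576 on the minus strand. The narrowest peak on either strand measured 83 bases. Peaks over 2000 bases numbered 79 on the plus strand and 86 on the minus strand.

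The 3 widest peaks all lay on the minus strand of chromosome 19. The widest measured 7781 bases, from 5837699 to 5845479. The next, from 5795782 to 5802734, measured 6953 bases, and the third, from 4798161 to 4804709, measured 6549 bases. The fourth, on the plus strand of chromosome 12 from 110782462 to 110788539, was 6078 bases wide. Minus-strand peaks of 5159 bases on chromosome 5 (115592973 to 115598131), 5079 bases on chromosome 7 (26030768 to 26035846) and 4794 bases on chromosome 11 (113055364 to 113060157) followed. None of these 7 peaks overlapped a peak on the other strand, and the nearest opposite-strand peak was between 27973 and 1469735 bases away.

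The remaining 18 of the 25 widest peaks measured 3569 to 4780 bases. On chromosome 11, they included plus-strand peaks at 69749221 to 69753684 and 102178120 to 102182406 and a minus-strand peak at 113609288 to 113613244. Chromosome 13 had 2 on the plus strand that were 6255 bases apart, at 98268752 to 98272320 and 98278576 to 98282887, and 1 on the minus strand at 6591495 to 6595404. Chromosome 3 had plus-strand peaks at 41366614 to 41370929 and 96361883 to 96365872. Single plus-strand peaks lay on chromosome 2 (165641882 to 165646452), chromosome 10 (80641102 to 80645454), chromosome 17 (23954921 to 23958777), chromosome 18 (75526892 to 75530915) and chromosome 19 (44377362 to 44381375). Single minus-strand peaks lay on chromosome 4 (129879334 to 129882985), chromosome 5 (33868545 to 33873007) and chromosome 15 (82681800 to 82685543). The other two were mitochondrial. Of the 25, 13 were on the plus strand and 12 on the minus strand, and 3 overlapped a peak of the opposite strand. Together they made up 2.10% of the covered bases.

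The mitochondrial genome, which is transcribed on both strands, had 6 peaks, 3 on each strand. Plus-strand peaks covered positions 1 to 2047, 2178 to 4338 and 10912 to 15559. Minus-strand peaks covered positions 3149 to 4065, 4846 to 5383 and 10851 to 15630. The last peak of each strand lay over the other for 4648 bases, the longest overlap in the data. Nuclei were isolated before capture, and no control library was compared. Whether YY1 bound this mitochondrial RNA or the RNA was carried over was therefore not tested. Chromosome Y had 1 peak on each strand, of 314 bases on the plus strand and 142 bases on the minus strand.

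Among the autosomes and chromosome X, chromosome 11 held the most peaks and chromosome X had the lowest density. Chromosome Y and the mitochondrial genome, with 2 and 6 peaks over short spans, were left out of the ranking by density. Chromosome 11, one of the gene-rich mouse chromosomes, had 1189 peaks, 9.86% of all (95% interval 9.34 to 10.41). Its density was 10.01 peaks per Mb, 2.09 times the median of the other 18 autosomes (4.79) and 1.57 times that of the next densest, chromosome 17 (6.36). The lowest autosomal density was 3.44 peaks per Mb, on chromosome 3. Chromosome X had 300 peaks, or 1.86 per Mb, which was 0.389 times the same autosomal median. Widths differed between chromosomes as well. The median was 422 bases on chromosome 11 (402 to 453), 237.5 bases on chromosome 13 (221 to 255) and 249.5 bases on chromosome X (230 to 283). The chromosome 11 share was 8.02% when same-strand peaks within 50 kb were counted once.

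**Figure D1:**
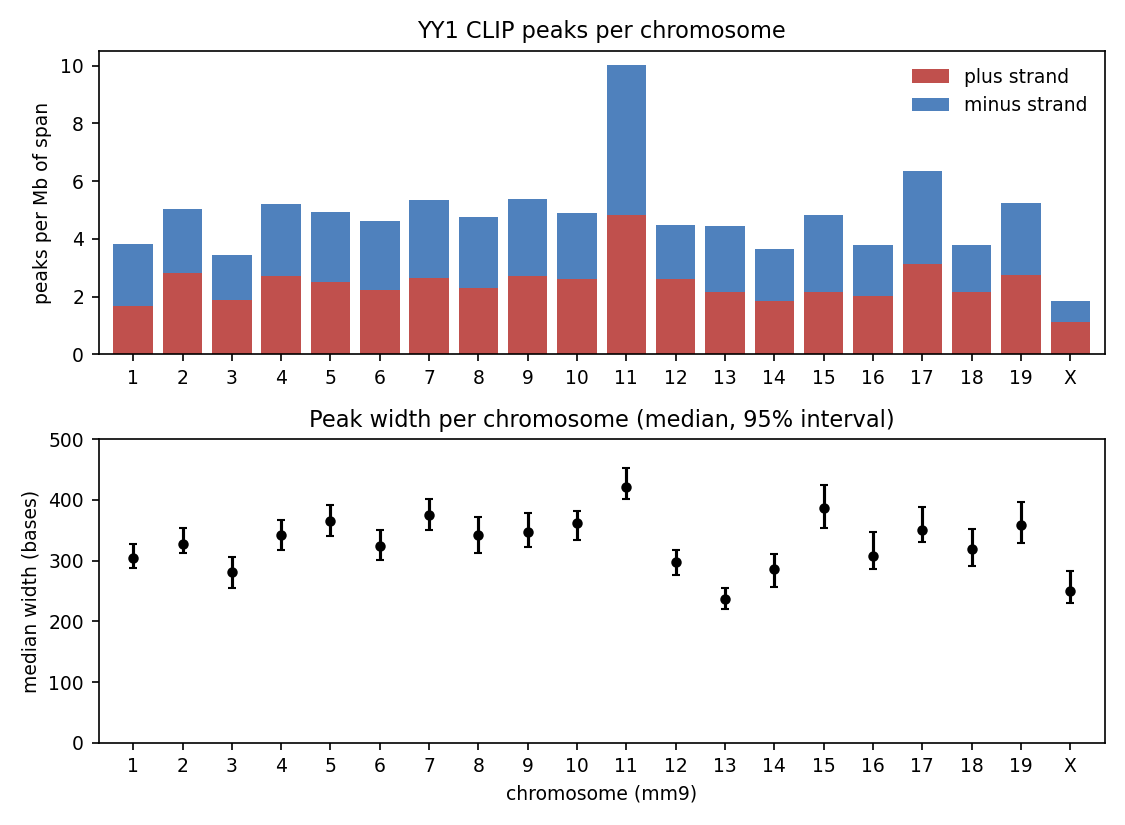
Peaks per Mb between the first and last peak of each chromosome (upper panel, bars stacked by strand) and median peak width in bases with its 95% interval (lower panel) for the autosomes and chromosome X of the 1 YY1 library. Chromosome 11 stands highest in both, at 10.01 peaks per Mb and 422 bases, and chromosome X has the lowest density, 1.86 peaks per Mb.

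Strand shares departed from 50% on some chromosomes, and on fewer of them when clustered peaks were counted once. The 95% interval of the plus-strand share excluded 50% on 6 of 19 autosomes. The highest autosomal share was 58.8% on chromosome 12 (54.5 to 63.1), and the lowest was 43.9% on chromosome 1 (40.3 to 47.6). Chromosome X had 59.3% (53.5 to 64.9). With same-strand peaks within 50 kb counted once, the share was 52.8% on chromosome 12 (47.0 to 58.6) and 56.4% on chromosome X (48.8 to 63.8), and only chromosome 1 of the autosomes excluded 50%, at 44.9% (39.9 to 49.9).

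Few peaks had a partner on the opposite strand at the same place, yet more than random placement gave. In 58 overlapping pairs, 58 plus-strand and 57 minus-strand peaks lay over each other, 0.954% of all peaks (0.788 to 1.14). Random placement gave a median of 33 overlapped peaks and at most 60, against 115 observed. The overlaps measured 41 to 4648 bases, with a median of 156.5. The longest after the mitochondrial one was on chromosome 11, where the plus-strand peak at 102178120 to 102182406 and the minus-strand peak at 102177629 to 102179783 had 1664 bases in common. On chromosome 5, peaks at 18775998 to 18776959 on the plus strand and 18775937 to 18776894 on the minus strand overlapped by 897 bases. In 46 of the 58 overlapping pairs, or 79.3% (66.6 to 88.8), the midpoint of the minus-strand peak had the lower coordinate.

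Peaks that lay next to each other on opposite strands were mostly divergent, the order that transcription in both directions from one element gives. Of 143 pairs with a gap of at most 2000 bases, 104 were divergent and 39 convergent, a divergent share of 72.7% (64.7 to 79.8). Random placement gave a median of 28 divergent pairs and at most 47, and a median of 28 convergent pairs and at most 45. Each minus-strand peak was instead moved by 5 to 50 kb, which keeps the density over longer stretches but thins out shorter clusters. The median was then 51 for both kinds, with at most 79 divergent and 74 convergent pairs. The number of divergent pairs lay above the highest of both sets, while that of convergent pairs lay above the median of the first and below the median of the second. The median gap was 497 bases in divergent pairs and 478 bases in convergent pairs. The terms divergent and convergent would change places if the lists were named for the strand opposite to the RNA. By gap, the divergent share was 51.9% of 27 pairs with a gap under 200 bases (31.9 to 71.3), 83.0% of 47 pairs from 200 to 500 bases (69.2 to 92.4), 82.5% of 40 pairs from 500 to 1000 bases (67.2 to 92.7) and 62.1% of 29 pairs from 1000 to 2000 bases (42.3 to 79.3). Between 2000 and 5000 bases it was 52.4% of 103 pairs (42.4 to 62.4), from 5000 to 10000 bases 58.2% of 122 pairs (48.9 to 67.1) and from 10000 to 20000 bases 60.7% of 178 pairs (53.1 to 67.9), where the interval again excluded 50%.

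The divergent pair with the largest summed width was on chromosome 6. Its minus-strand peak ran from 113025926 to 113027010 and its plus-strand peak from 113027219 to 113029331, with a gap of 208 bases. On chromosome 11, a minus-strand peak at 93746222 to 93746740 and a plus-strand peak at 93746759 to 93748713 were 18 bases apart. On chromosome 13, peaks at 58502475 to 58503817 on the minus strand and 58503988 to 58504820 on the plus strand were 170 bases apart. On chromosome 17, peaks at 34167924 to 34168576 on the minus strand and 34168817 to 34170130 on the plus strand were 240 bases apart. Chromosomes 1 and 11 had 11 divergent pairs each, chromosome 6 had 10, and chromosome X had 2. On chromosome 1, successive divergent pairs had nearly equal gaps of 535, 539, 538 and 535 bases. Such pairs may not be independent, and the divergent share was not recomputed without them.

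**Figure D2:**
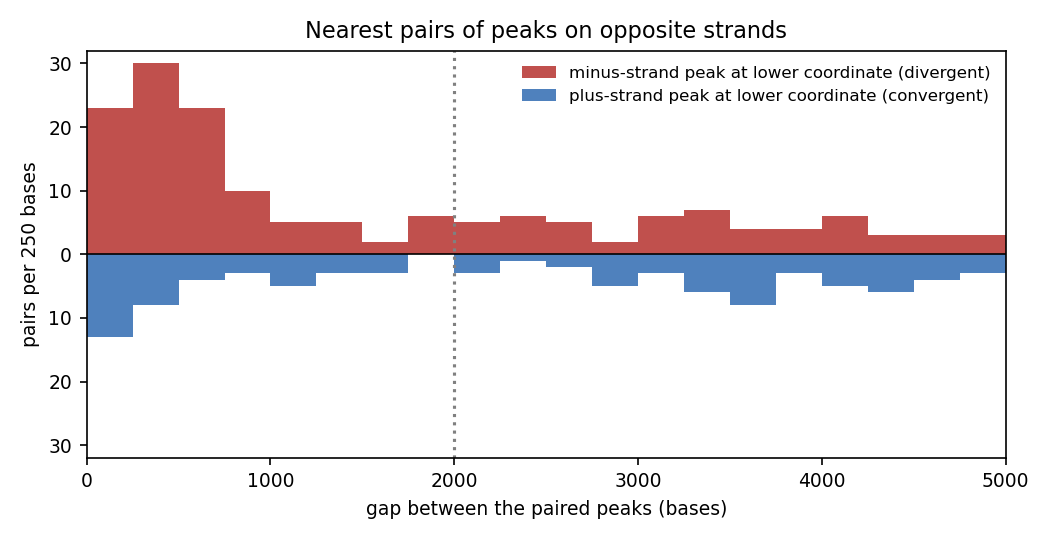
Number of nearest opposite-strand peak pairs per 250 bases of gap (x axis, bases), with divergent pairs drawn upward and convergent pairs downward and the 2000-base limit dotted. Up to that limit 104 pairs were divergent and 39 convergent, and from 2000 to 5000 bases 54 were divergent and 49 convergent.

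Peaks gathered along the same strand. Single peaks with no same-strand neighbour within 10 kb made up 64.2% of the total (63.4 to 65.1). Clusters of 3 or more peaks numbered 455 and held 1647 peaks, or 13.7% (13.1 to 14.3). Under random placement such clusters held a median of 34 peaks and at most 67. That placement did not keep the regional density of peaks, and moves that keep it were not run for clusters. The comparison therefore cannot show whether peaks gathered beyond their regional density. The cluster with the most peaks was on the minus strand of chromosome 8, from 126062639 to 126147645, where 50 peaks with a median width of 165.5 bases lay within 85.0 kb. They were 15.8% of the minus-strand peaks of that chromosome, and no plus-strand peak lay among them. Minus-strand clusters of 9 peaks lay on chromosome 1 (172994244 to 173010819, median width 133 bases) and chromosome 13 (23517470 to 23545385, 124 bases). A plus-strand cluster of 8 peaks lay near the latter on chromosome 13 (23609066 to 23626292, 122 bases). The other clusters of 8 peaks held wider ones. These were the plus strand of chromosome 10 (82836121 to 82897796, median width 1591.5 bases), the minus strand of chromosome 1 (134894704 to 134930981, 468.5 bases) and the plus strand of chromosome 14 (8736898 to 8784098, 475.5 bases).

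When gaps of up to 50 kb were allowed, the cluster with the second most peaks was on the plus strand of chromosome 6. It had 37 peaks over 513 kb, from 33201200 to 33714166, with a median width of 427 bases. A minus-strand cluster on chromosome 11 (69481053 to 69667074) held 17 peaks with a median width of 678 bases, and one on chromosome 7 (20117204 to 20341914) held 16 with a median width of 549.5 bases.

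**Figure D3:**
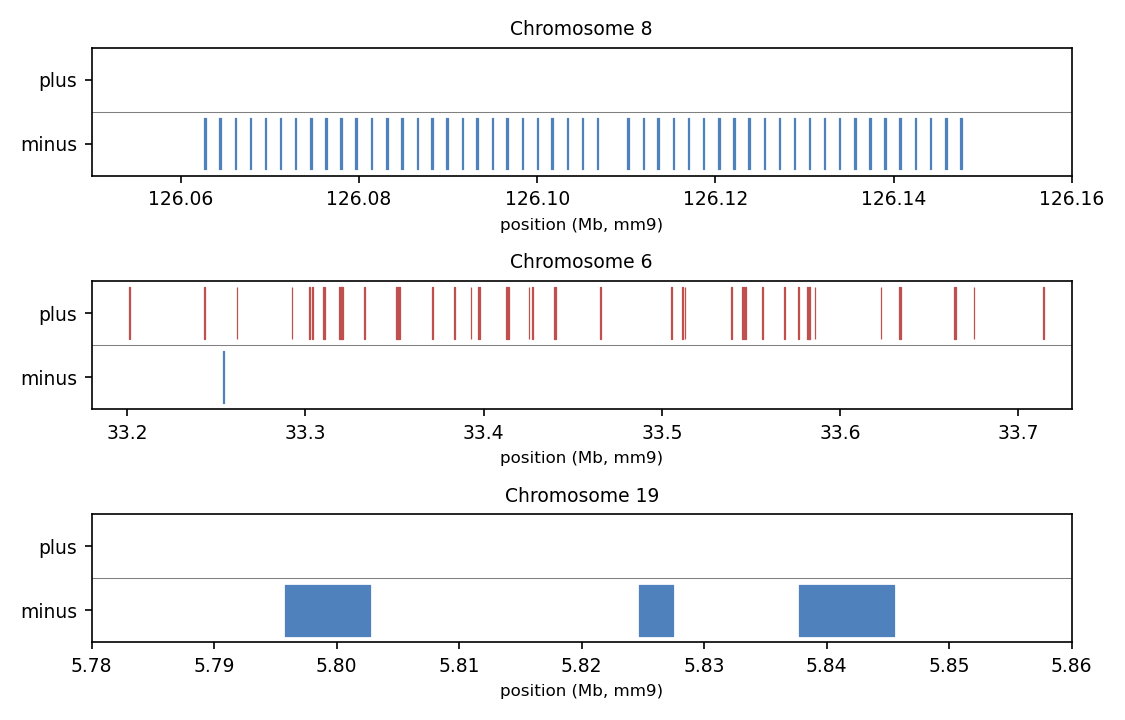
Peaks of the YY1 library on the plus (upper row) and minus (lower row) strand against mm9 position in Mb, in 3 regions. The 50 minus-strand peaks on chromosome 8 are narrow, those on chromosome 6 are 37 plus-strand peaks over 513 kb, and the chromosome 19 region holds the widest peaks, of 7781 and 6953 bases.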

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

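Of 39 alternative values, 19 stayed within the main interval, or within 1.5 times the main count, and 20 did not. A turn of direction was looked for in the divergent share only, and none of its alternatives fell below 50%. Some outcomes follow from the change itself. Keeping the wider 50% of peaks must lower the count and raise the median width, and leaving out a few peaks can hardly move a share. The tally is therefore not a measure of robustness. With the wider 50% of peaks of each strand, 6036 peaks with a median width of 573 bases were left. The share on chromosome 11 was then 12.2% and that on chromosome X 1.77%, opposite-strand overlaps took in 0.596% of peaks, the divergent share was 92.9% of only 28 pairs, and 11.1% of peaks lay in clusters of 3 or more. Joining peaks within 100 bases gave 12.1% in such clusters, a gap limit of 1 kb gave 1.59%, and one of 50 kb gave 46.5%. Counting an overlap only from 50% of the shorter peak gave 0.763% of peaks, and counting gaps of up to 500 bases as shared gave 2.25%. The divergent share was 64.2% with gaps of up to 5000 bases. The circular shift gave 33 overlapped peaks, close to the 32 of a second set of placements. Leaving out the mitochondrial chromosome kept the number of peaks, plus-strand share, median width, overlap share, divergent share and cluster share within these bounds; it was not run for the chromosome shares or the placements. Alternatives chosen after seeing the data were these. Counting same-strand peaks within 50 kb once left 6385, with 8.02% on chromosome 11 and 2.80% on chromosome X. Gaps of up to 200 bases gave a divergent share of 51.9% over 27 pairs. Moving each minus-strand peak by 5 to 50 kb keeps the density over longer stretches but thins out shorter clusters. These moves gave a median of 56 overlapped peaks and at most 96, still under the 115 observed. They also gave a median of 51 divergent and 51 convergent pairs, against 28 of each under random placement. The 39 convergent pairs thus turned from above to below the median. Leaving out the 50-peak array of chromosome 8 gave 13.3% of peaks in clusters. Alternatives for peaks in genes, gene strand and gene lists were not run, since those results need an mm9 annotation. No paired analysis was possible because a single library was analysed. Read depth is unknown, so a stretch without a peak is not shown to lack bound RNA.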

Other observations

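The regions with the most peaks were of more than one kind, a pattern noticed in the data. Joined across gaps of up to 50 kb, 38 same-strand clusters held 10 or more peaks each. In 8 of them, with 129 peaks, the median width was under 150 bases, between 123 and 138, against 336 bases over all peaks. These 8 lay on 4 chromosomes, and at 3 loci a plus-strand and a minus-strand cluster overlapped. The first locus was on chromosome 13, with 21 plus-strand peaks from 23488950 to 23673887 and 23 minus-strand peaks from 23453508 to 23714426. The second was on chromosome 3, with 17 plus-strand peaks from 96125999 to 96301829 and 15 minus-strand peaks from 96138452 to 96305445. The third was on chromosome 1, with 13 peaks on each strand, from 172958099 to 173041711 on the plus strand and from 172964027 to 173032057 on the minus strand. Another narrow cluster on chromosome 13 had 16 plus-strand peaks from 21253274 to 21414805, and one on chromosome 11 had 11 from 68829624 to 68937875. By contrast, 26 of the 38 clusters had a median width above that of all peaks. The widest were 13 plus-strand peaks on chromosome 4 from 137024671 to 137214646, with a median of 1215 bases, and 11 on chromosome 10 from 82836121 to 82940971, with a median of 1137 bases. Which transcripts lie in these regions was not examined here.

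Of the tests that follow, those with moves of 5 to 50 kb, on the order of the overlapping pairs, on the pairs with a gap under 200 bases, on the 100 widest peaks and on the spacing of the chromosome 8 peaks, and the removal of parts by peaks per Mb, were chosen after the data were seen. The design names no second group with values, so no biological explanation was tested.

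Opposite-strand neighbours within 2000 bases were divergent in 104 of 143 pairs. Gathering of both strands in the same long regions would give as many divergent pairs after each minus-strand peak is moved by 5 to 50 kb. However, 1000 such moves gave a median of 51 and at most 79, while their convergent pairs had a median of 51 against 39 observed. The moves thin out shorter clusters, so they do not test gathering within those. Reads assigned to the wrong strand would put overlapping pairs in no preferred order if they lay evenly over their source. The minus-strand peak came first in 79.3% of the overlapping pairs (66.6 to 88.8). Wrong-strand reads would also mirror the strongest peaks. The mark was an overlapped share at least 5 times that of the others, with width standing in for signal. The share was 1.41% in the widest 10% of peaks against 0.903% in the others, a ratio of 1.56 (0.938 to 2.61). Among the 100 widest, with the 2 mitochondrial peaks, the share was 5% (1.64 to 11.3), a ratio of 5.54, which lay above the mark. Over the 98 nuclear ones it was 3.06% (0.636 to 8.69), a ratio of 3.39. Of these nuclear peaks 3 overlapped, where the moves gave a median of 2 and at most 6. No interval was computed for these ratios, so the 100 widest do not decide the question. The tests of order and mirroring used overlapping peaks, which were left out of the 143 pairs. They therefore do not settle whether wrong-strand reads made those pairs. For the overlapping pairs, the order argues against wrong-strand reads lying evenly over their source as the whole cause. Wrong-strand reads shifted to 1 side of their source would give a fixed order, so the test cannot exclude them. In the chromosome 5 pair with 897 bases in common, both ends of the minus-strand peak had the lower coordinate. Wrong-strand reads as a part of the cause at single loci also stay open, as do the 27 pairs with a gap under 200 bases (51.9% divergent, 31.9 to 71.3). Transcription in both directions from a single promoter or enhancer and head-to-head genes also stay open. Neither was tested, for want of an mm9 annotation.

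The 50 minus-strand peaks on chromosome 8 were evenly spaced. In 48 of the 49 steps from one start to the next the spacing was 1617 to 1754 bases, with a mean of 1697 ± 27.6 (SD), and the remaining step, 3394 bases, was 2.00 times the median spacing of 1698. Peak widths were 162 ± 16.4 bases (SD). The coefficient of variation over all 49 steps was 0.141, below the 0.179 to 1.30 of the other 52 clusters of 5 or more peaks. That of the widths was 0.101 and was not the lowest. In the other clusters it had a minimum of 0.0738 and a median of 0.491. The spacing is consistent with a tandem repeat with 1 unit lacking a peak, but whether reads from 1 copy were spread over near-identical copies cannot be told apart from binding at each copy, since neither the sequence nor the handling of reads that map to several places was at hand. The 50 peaks may therefore stand for fewer RNAs.

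Chromosome 11 had the highest peak density among the autosomes and chromosome X. The density did not rest on 3 parts of 10 Mb alone. Without the 3 parts that held the most peaks it was 8.49 peaks per Mb, against at most 4.45 on the other autosomes treated alike (chromosome 7). Without the 3 parts with the most peaks per Mb it was 8.84, against at most 4.53. A longer dense stretch is not excluded by these removals. The parts from 10 to 50 Mb had 3.2 to 6.5 peaks per Mb, and the other parts had 9.2 to 19.4. Peaks of chromosome 11 were 1.24 times as wide as those of the other autosomes in geometric mean. At matched local density in 6 classes the ratio was 1.14 (1.04 to 1.25, 2000 bootstrap draws over windows of 1 Mb). The classes were broad, so differences in density within a class may account for part or all of this remainder. The interval makes no allowance for the choice of chromosome 11 after its values were seen. Chromosome 15 had a higher matched ratio, 1.17. In 12 of 13 parts chromosome 11 lay above the median part of the other autosomes, 4.11 peaks per Mb. The remaining part, from 10 to 20 Mb, had 3.2. Extra copies would raise all parts alike, but the density each part would have without them is unknown. Both extra copies of the chromosome in these cells and a high density of transcribed genes stay open. Those explanations cannot be told apart here, as no control library or gene count was used.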
